A study of Sparus aurata with 16 samples.

How the data were processed

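Total RNA from 16 pools of VSa16 cells was labelled with Cy3 and hybridised one sample per array to a Sparus aurata oligonucleotide microarray (Agilent design 016251). Per the labels' protocols, cells grew in medium with 10% serum and 2 mM glutamine. F2 cells received a FLAG-tagged seabream FHL2 coding sequence in a plasmid and were kept for 3 weeks in 300 µg/ml geneticin before resistant clones were taken on. Whether WT cells carried an empty plasmid or met geneticin is not given in the sources used here. A difference between F2 and WT therefore covers FHL2, the plasmid, the selection and the origin of F2 from resistant clones together. The labels call the replicates pools of cells. They do not say whether the pools came from separate cultures, so p-values measure the spread between these pools, which may be partly technical. The groups WT_T0, WT_T4, F2_T0 and F2_T4 held 4 arrays each, and no 2 arrays had identical values.

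The authors deposited 1 scanner file per array, written by Agilent Feature Extraction 9.5 per the file headers. These files hold a linear intensity per spot on a single green channel, and the processed intensity used here was background-subtracted by that software, per the file headers. The deposited series table holds further intensity values of the same arrays on a linear scale. Its columns had medians between 112.9 and 175.9 and rank correlations with the scanner values between 0.997 and 1.00. The ratio of the table's values to the scanner values changed with brightness, so its normalization stays unknown, and it was used only as an alternative. The scanner files also give flags and identify 9 slides and 6 scan days, numbered here in order.

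Each array carried 40816 features, of which 1417 were controls and were left out. The remaining 39399 probes have 19732 identifier stems, and all are described as unknown in the files, with the gene name set to the probe name. None of these identifiers was found in the table of 32006 gene rows for assembly fSpaAur1.1. For this reason the 27 gene lists fixed before the data were examined, which included markers of other cell types, could not be applied, and no list was tested. The planned report of FHL2 in every array and of a panel of bone and epithelial-mesenchymal genes was not possible either. No gene name was inferred from a probe sequence.

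Intensities were taken as log2 of the processed signal minus the log2 of each array's 75th percentile. Values of spots with an outlier flag were left out (85 values among the tested probes), and saturated spots were kept (at most 1 per array). A probe was tested if it was well above background on at least 4 of the 16 arrays, which left 29832 probes of 16501 stems and set aside 9567. The test was limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes on a model with 1 mean per group and 12 residual degrees of freedom. It was two-sided, with Benjamini-Hochberg adjustment within each of 5 contrasts and a threshold of 0.05. The 5 contrasts were F2 over WT at T0 and at T4, T4 over T0 in WT and in F2, and the interaction. The 75th percentile scaling assumes that this percentile did not change, and the median log2 fold change over all tested probes then lay between -0.10 and 0.08 in the 5 contrasts. The number of arrays limits the precision: the median SE of a log2 fold change was 0.17, and 0.24 for the interaction.

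The rule for named features was fixed for annotated genes before the data were examined. As no gene was annotated, it was adapted afterwards to identifier stems: the stem's brightest tested probe had to pass the threshold, be well above background on all arrays compared, separate the 2 groups' arrays without overlap (not asked for the interaction), and share its sign with the stem's other tested probe. The 10 largest rises and 10 largest falls per contrast, 5 each for the interaction, were kept, and the first 2 of each are given. A probe not well above background on any array of a group has only a bound there. The bound took the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's signal and the lowest signal of any probe well above background.

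The pipeline was tested on simulated data with the real probe means and residual SDs, 29832 probes and 200 changed probes per contrast. Of the changes of 1.5-fold, 2-fold and 4-fold in the F2 difference at T0, 23.9%, 65.7% and 87.9% were recovered in the right direction. For the interaction the shares were 13.4%, 46.3% and 69.7%. The simulation changed far fewer probes than were called in the real data, and it held no slide or scan day differences. These shares therefore do not carry over to the real comparisons, and false calls due to slide or scan day were not tested.

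Slide and scan day were each tested as a block. WT_T0 had 3 arrays on scan day 6 and 1 on day 4, and F2_T0 had 2 on day 5 and 1 each on days 2 and 3. WT_T4 had 2 on day 4 and 1 each on days 1 and 3, and F2_T4 had 2 on day 6 and 1 each on days 4 and 5. Alternatives set before the data were examined were quantile and median scaling, normexp background correction with an offset of 50, the series table, other filters on dim probes, replicate number, slide and scan day as blocks, fits on the compared groups alone, array weights, a trended robust prior, stem averages and leaving out each array. Random blocks for slide and scan day, a normexp fit without spots darker than their surroundings, a fit without the arrays of scan day 4 and a looser detection rule were chosen after seeing the data.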

Results

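Gene expression was measured in VSa16, a pre-osteoblast cell line (cells committed to the bone lineage that have not yet formed mature osteoblasts) of the gilthead seabream, Sparus aurata. Control cells (WT) were set against cells (F2) transfected with the seabream coding sequence of FHL2, a LIM-domain protein that acts as a transcriptional cofactor and cytoskeletal adaptor. The series set out to learn whether excess FHL2 moves these cells toward a state like an epithelial-mesenchymal transition, in which cells lose epithelial traits and gain mesenchymal ones. Both lines were sampled at the start of confluence (T0) and after 4 weeks of confluence (T4). Each of the 4 groups held 4 pools of cells, hybridised to 16 one-colour oligonucleotide arrays. Each array carried 39399 probes of 60 bases, of which between 58.97% and 79.11% were well above background on one array. The 75th percentile of the processed intensity lay between 556.4 and 1853. A total of 29832 probes were well above background on at least 4 arrays and were tested. The files pair no probe with a gene, so FHL2 itself and every other gene stay unnamed, and features are given by probe identifier and sequence. Most transcripts have 2 probes that share an identifier stem and end in _1 or _2.

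Arrays of one group mostly correlated more closely than arrays of different groups. Within groups, Pearson correlations across probes ranged from 0.957 (F2_T4) to 0.993 (WT_T0), with group medians of 0.980 to 0.989. Between groups they ranged from 0.900 to 0.976, with a median of 0.945. The first principal component held 36.4% of the variance and ran from WT_T4 through WT_T0 and F2_T4 to F2_T0. The second held 24.9% and set the scan day 6 arrays (37.8 to 116.4) above all others (-83.0 to -0.96). Those arrays belonged to WT_T0 and F2_T4 only. WT_T0 replicate 3 and F2_T4 replicate 1, both of scan day 4 and slide 4, lay far below the other arrays of their groups on this component. The third component held 18% and ran from the T0 arrays of both lines (37.9 to 48.5) through WT_T4 (-7.8 to 5.2) to F2_T4 (-93.2 to -77.7).

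**Figure D1:**
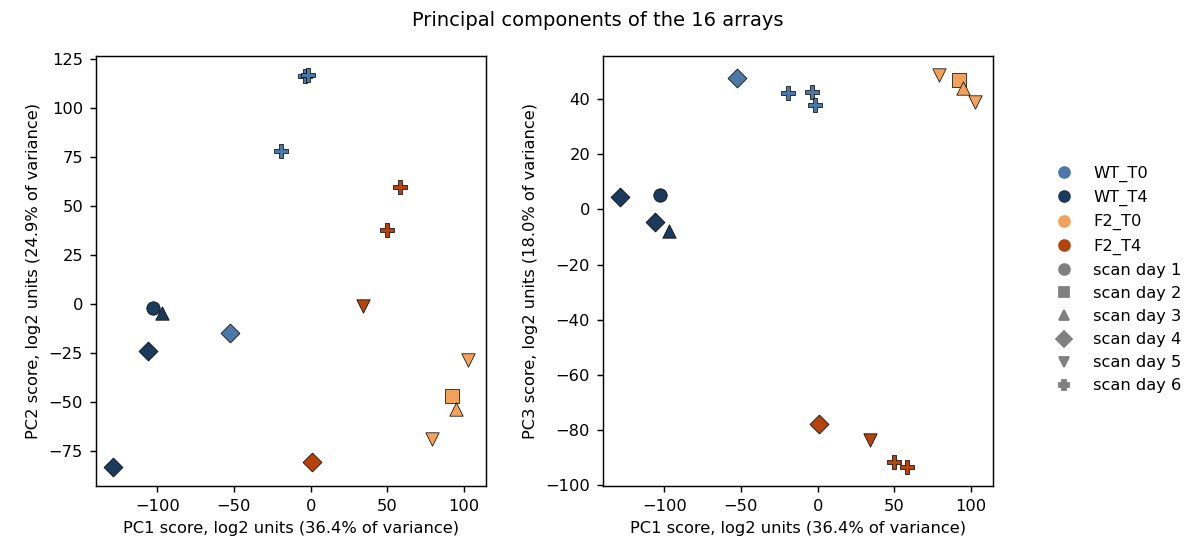
Scores of the 16 arrays on principal components 1, 2 and 3 of the tested probes (log2 units, share of variance on each axis), coloured by group and shaped by scan day. On component 1 the F2_T0 arrays lie highest (78.9 to 102.6) and the WT_T4 arrays lowest (-128.6 to -97.2). On component 2 only the scan day 6 arrays have positive scores, and the scan day 4 arrays of WT_T0 (-14.9) and F2_T4 (-80.5) lie below the other arrays of their groups.

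The first comparison asked how the transfected line differed from the control line at the start of confluence. Of the 29832 probes, 6907 were higher and 6775 lower in F2 at an adjusted p under 0.05, together 45.9%. At least a 2-fold difference was seen in 2331 higher and 2882 lower probes. Which side held more calls depended on the processing, with 7914 higher and 5671 lower after median scaling, and 5283 and 7119 after normexp background correction without spots darker than their surroundings. The largest changes are named among probes that met a set of conditions, which included a signal well above background on every array compared. Among these the falls reached 149.8-fold and the rises 52.4-fold. Probe SAPD09339_2 (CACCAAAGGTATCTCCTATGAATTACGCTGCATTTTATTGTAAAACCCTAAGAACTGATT) fell from 4.17 ± 0.05 in WT to -3.06 ± 0.29 in F2 (log2 relative to the array's 75th percentile, mean ± SD, n = 4), a log2 fold change of -7.23 (SE 0.15, limma adjusted p = 3.16e-13). SAPD24932_1 (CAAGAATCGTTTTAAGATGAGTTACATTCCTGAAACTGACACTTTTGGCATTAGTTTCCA) fell from 4.27 ± 0.17 to -2.86 ± 0.16, a log2 fold change of -7.14 (SE 0.15, limma adjusted p = 3.16e-13). SAPD17564_2 (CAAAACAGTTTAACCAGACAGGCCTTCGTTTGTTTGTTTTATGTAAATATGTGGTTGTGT) rose from -1.94 ± 0.18 to 3.77 ± 0.14, a 52.4-fold increase (log2 5.71, SE 0.13, limma adjusted p = 6.49e-13). SAPD07899_2 (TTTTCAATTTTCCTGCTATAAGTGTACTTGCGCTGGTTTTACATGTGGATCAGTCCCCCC) rose from -2.35 ± 0.11 to 3.28 ± 0.07, a 49.2-fold increase (log2 5.62, SE 0.14, limma adjusted p = 1.16e-12). In each case the partner probe with the same identifier stem changed by a similar amount, with log2 fold changes of -7.04, -7.09, 5.58 and 5.43 in the order given.

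Some probes differed in whether they rose above background at all. At T0, 174 probes were well above background on all 4 F2 arrays and on none of the 4 WT arrays, with a median difference of at least 2.31-fold where a bound above 1 could be set. In the other direction, 118 probes were seen on all WT arrays and on no F2 array, with a median of at least 5.97-fold and a maximum of at least 184-fold. Such bounds compare the mean of the brighter group with, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal that counted as well above background.

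The calls at T0 rest on arrays that shared no slide and no scan day between WT and F2. No value within one slide or one scan day could therefore be had for this comparison. With scan day as a block in the same model, 4331 probes were higher and 4127 lower, and with slide as a block 7295 were called. Under the scan day block, 4203 and 4048 of the calls were also made in the same direction without it, and 0 were called in opposite directions. The 4 probes named above kept log2 fold changes of -7.20, -7.30, 5.73 and 5.77 under the scan day block, with limma adjusted p values of at most 1.59e-06. Either block reaches this comparison only by way of the T4 arrays, which share days and slides with both T0 groups. F2_T0 replicate 2, alone on its day and slide, adds nothing to the blocked values. F2_T0 replicate 1, alone on its slide, adds nothing to those with slide as a block. The blocked values are therefore indirect and do not replace a comparison within one day.

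After 4 weeks of confluence the 2 lines still differed widely. Here 5986 probes were higher and 7002 lower in F2, together 43.5% of those tested, and 1842 and 2758 of them differed at least 2-fold. The surplus of lower calls depended on the scaling: after quantile normalization 7297 were higher and 6230 lower. Among probes that met the same conditions, SAPD09662_1 (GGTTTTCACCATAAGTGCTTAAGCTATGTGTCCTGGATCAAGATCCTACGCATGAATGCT) showed the largest fall, from 4.75 ± 0.29 in WT to -4.79 ± 0.32 in F2, a log2 fold change of -9.54 (SE 0.20, limma adjusted p = 3.51e-13). SAPD09339_2, among the deepest falls at T0, was lower again, with a log2 fold change of -9.20 (SE 0.15, limma adjusted p = 3.38e-14). In the control line this transcript rose over the 4 weeks from 4.17 to 6.45, while in F2 it measured -3.06 at T0 and -2.75 at T4 (adjusted p = 0.122). SAPD01661_2 (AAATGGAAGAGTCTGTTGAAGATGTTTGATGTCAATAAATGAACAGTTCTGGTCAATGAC) was 88.5-fold higher in F2 (log2 6.47, SE 0.29, limma adjusted p = 5.53e-10), up from a log2 difference of 2.70 at T0. SAPD07899_2 was 30.6-fold higher (log2 4.93, SE 0.14, limma adjusted p = 5.16e-12), after 49.2-fold at T0. Well above background on every F2_T4 array and on no WT_T4 array were 108 probes, and 188 probes showed the opposite pattern with a median of at least 4.4-fold. In total, 27015 to 31167 probes were detected per WT_T4 array, against 25297 to 28744 per F2_T4 array. That alone may favour detection in WT only.

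At T4 the comparison could also be made inside one scan day. The log2 fold changes from 1 F2_T4 and 2 WT_T4 arrays of scan day 4 were set against those from the 5 arrays of the other days, and correlated at r = 0.705 across probes, with 74.1% of signs shared. Of the 13478 probes called without that day, 88.5% kept their sign inside it. Their median log2 fold changes inside and outside that day were 0.65 and 0.86 for rises and -0.57 and -0.94 for falls, where the choice of probes by the outside arrays itself favours larger values outside. Probes are not independent replicates, so such correlations describe the arrays. On the 1 slide that held both groups, the same comparison gave r = 0.628. With scan day as a block, 5016 probes were higher and 5177 lower, and with slide as a block 8352 were called. WT_T4 replicate 3, alone on its day and slide, adds nothing to any blocked value. WT_T4 replicate 2, alone on its slide, adds nothing to values with slide as a block.

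Across both times, 36 probes were well above background on all 8 F2 arrays and on none of the 8 WT arrays, and 29 showed the reverse. The F2-only probes differed by a median of at least 4.26-fold and at most by at least 33.8-fold. The WT-only probes differed by a median of at least 9.12-fold and at most by at least 119-fold. Both probes of a stem were present for 5 of the 31 F2-only stems and 4 of the 25 WT-only stems. Of the 2450 ways to divide the 16 arrays into 8 and 8 with 4 of each time on either side, the real division gave 65 such probes, no other gave more than 23, and the median of the others was 0 (permutation p = 0.000408, the smallest these divisions can give). These divisions take no account of slide or scan day, which were unevenly spread over the lines.

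The F2 difference at T0 and the F2 difference at T4, which share no array, overlapped in part. Both times showed the same 3245 probes higher, where 1386 would be expected of independent lists, and the same 3576 lower, against 1590 expected. Opposite calls were fewer than independent lists would give, with 529 probes higher at T0 and lower at T4 (1621 expected) and 557 the other way (1359 expected). Across all tested probes the 2 sets of log2 fold changes correlated at r = 0.387 (Spearman 0.219), and at r = 0.525 (Spearman 0.396) with scan day as a block. Without the 4 arrays of scan day 4 the correlation was 0.252, and its jackknife SD was 0.175. That choice of arrays put WT_T0 on scan day 6 alone, and 2 F2_T4 arrays stayed on that day. A day 6 difference then enters the F2 differences at T0 and T4 with opposite signs, which alone would lower their correlation. Of the 2331 probes at least 2-fold higher in F2 at T0, 55% were also called higher at T4, with a median log2 fold change of 0.62 after 1.48 at T0. Of the 2882 at least 2-fold lower at T0, 58.7% were also called lower at T4, with medians of -0.76 and -1.50. Selecting at T4 gave much the same: of the 1842 probes at least 2-fold higher and 2758 at least 2-fold lower at T4, 59.7% and 53.6% were called in the same direction at T0. Their medians were 1.49 and -1.66 at T4 and 0.88 and -0.69 at T0, so the smaller medians at the other time do not show a fading of the difference.

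**Figure D2:**
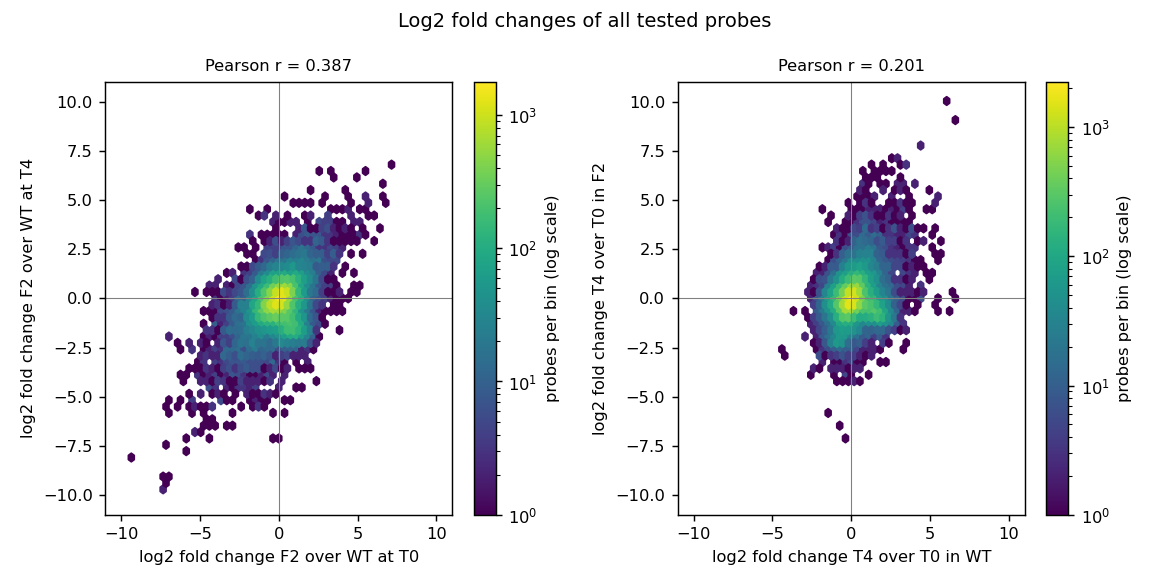
Log2 fold changes of the 29832 tested probes, with colour giving the number of probes per bin on a log scale. The left panel sets F2 over WT at T4 against the same ratio at T0 (r = 0.387), and the right panel sets T4 over T0 in F2 against the same ratio in WT (r = 0.201).

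The next comparison asked what 4 weeks of confluence changed in control cells. In WT, 6407 probes were higher and 4864 lower at T4 than at T0, and 2679 and 1185 of them changed at least 2-fold. Which side held more calls depended on the scaling: after quantile normalization 5729 were higher and 6214 lower. SAPD24866_2 (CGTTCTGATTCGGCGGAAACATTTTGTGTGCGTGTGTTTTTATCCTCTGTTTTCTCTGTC) rose 29.9-fold, from 3.12 ± 0.26 to 8.03 ± 0.31 (log2 4.90, SE 0.17, limma adjusted p = 1.34e-10). SAPD11174_1 (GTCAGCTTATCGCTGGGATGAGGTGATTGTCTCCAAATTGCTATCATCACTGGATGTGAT) rose 23.8-fold, from -3.70 ± 0.13 to 0.87 ± 0.22 (log2 4.57, SE 0.10, limma adjusted p = 4.67e-12). In F2 the same 2 probes rose by 1.36 and 0.73 on the log2 scale, and the interaction was -3.54 and -3.84 (adjusted p = 1.44e-07 and 1.13e-09). SAPD07918_1 (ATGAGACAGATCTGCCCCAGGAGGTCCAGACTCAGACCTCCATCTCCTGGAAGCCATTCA) showed the largest fall by the same rule, from 3.06 ± 0.57 to -1.12 ± 0.86 (log2 -4.17, SE 0.52, limma adjusted p = 3.56e-05). SAPD06441_2 (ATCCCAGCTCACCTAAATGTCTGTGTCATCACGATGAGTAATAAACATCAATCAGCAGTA) fell from 0.66 ± 0.45 to -2.31 ± 0.17 (log2 -2.97, SE 0.21, limma adjusted p = 1.64e-07). Both also fell in F2, with log2 fold changes of -2.96 and -1.89. Appearance above background was one-sided in WT, with 159 probes seen on all T4 arrays and no T0 array and 2 probes seen the other way round. The WT_T0 arrays also detected fewer probes in total, 23235 to 28869 per array against 27015 to 31167 on the WT_T4 arrays.

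This was the comparison most altered by scan day among the 4 pairwise ones. With scan day as a block, 3024 probes were higher and 2562 lower, so the number of calls fell from 11271 to 5586, and with slide as a block it was 3625. Inside scan day 4, log2 fold changes of 2 WT_T4 arrays over 1 WT_T0 array correlated at r = 0.565 with those from the other 5 arrays, and the correlation inside 1 slide was 0.483. Of the 11721 probes called without that day, 85.5% kept their sign inside it, with median log2 fold changes inside and outside of 0.45 and 0.98 for rises and -0.42 and -0.83 for falls. The choice of probes favours larger values outside here too. For time in F2, inside scan day 5, the same kind of choice left a smaller gap. The medians there were 0.91 inside and 1.03 outside for rises, and -0.77 and -0.84 for falls. The wider gap in WT may therefore include a part due to scan day, which was not tested.

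Without a block, the transfected line changed over the 4 weeks in about as many probes as the control line. The scan day block left more calls in F2 (9037) than in WT (5586). In F2, 6044 probes were higher and 5871 lower at T4, and 2432 and 1730 of them changed at least 2-fold. After median scaling 5305 were higher and 6341 lower. Among probes that met the conditions for naming, the largest rises exceeded those of the control line. SAPD00124_2 (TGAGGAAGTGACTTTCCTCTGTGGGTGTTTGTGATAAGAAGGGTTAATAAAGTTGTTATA) rose 200.1-fold, from -4.26 ± 0.17 to 3.38 ± 0.14 (log2 7.64, SE 0.11, limma adjusted p = 5.53e-15), against a rise of 4.34 in WT. SAPD18662_1 (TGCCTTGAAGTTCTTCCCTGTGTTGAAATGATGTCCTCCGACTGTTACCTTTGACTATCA) rose 124.3-fold, from 0.39 ± 0.18 to 7.35 ± 0.13 (log2 6.96, SE 0.16, limma adjusted p = 5.91e-13). It rose by 2.95 in WT, from 3.99 to 6.94, so that a log2 difference between the lines of -3.59 at T0 was 0.41 at T4 (adjusted p = 0.0554). SAPD15405_1 (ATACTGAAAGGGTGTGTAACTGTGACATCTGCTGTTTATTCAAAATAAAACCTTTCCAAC) fell from 1.104 ± 0.21 to -5.22 ± 0.68 (log2 -6.32, SE 0.25, limma adjusted p = 9.95e-11). SAPD05063_2 (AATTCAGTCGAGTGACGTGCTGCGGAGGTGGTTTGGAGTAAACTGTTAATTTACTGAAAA) fell from 3.12 ± 0.27 to -1.13 ± 0.13 (log2 -4.25, SE 0.16, limma adjusted p = 7.46e-11). In WT these 2 probes fell by 0.72 and 0.50. On all F2_T4 arrays and on no F2_T0 array, 223 probes were well above background, by at least 3.29-fold at the median and at least 260-fold at most, and 73 were seen the other way round.

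With scan day as a block, 4510 probes were higher and 4527 lower in F2 at T4, and with slide as a block 7511 were called. Inside scan day 5, log2 fold changes of 1 F2_T4 array over 2 F2_T0 arrays correlated at r = 0.879 with those from the other 5 arrays, and 99.4% of the 8984 probes called without that day kept their sign inside it. Their medians inside and outside, chosen in the same way, were 0.91 and 1.03 for rises and -0.77 and -0.84 for falls. Inside 1 slide the correlation was 0.831.

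The time courses of the 2 lines had a part in common. Both lines showed the same 2728 probes higher at T4 (1298 expected of independent lists) and the same 2140 lower (957.2 expected). Opposite calls numbered 467 for higher in WT and lower in F2 (1261 expected) and 392 for the reverse (985.5 expected). The log2 fold changes correlated at r = 0.201 (Spearman 0.129), and at r = 0.339 (Spearman 0.262) with scan day as a block. Without the 4 arrays of scan day 4 the correlation was 0.0256, and without F2_T4 replicate 1 alone it was 0.0583, while slide as a block gave 0.413. Leaving out scan day 4 put WT_T0 on day 6 alone and WT_T4 on days 1 and 3. Of F2_T4, 2 arrays stayed on day 6. A day 6 difference then enters the time effects of WT and F2 with opposite signs, which alone would lower their correlation. Whether it did was not tested, and both blocks raised the correlation. Its size was therefore poorly determined. Of the 2679 probes that rose at least 2-fold in WT, 35.3% were also called higher in F2. Of the 2432 that rose at least 2-fold in F2, 55.6% were also called higher in WT.

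**Figure D3:**
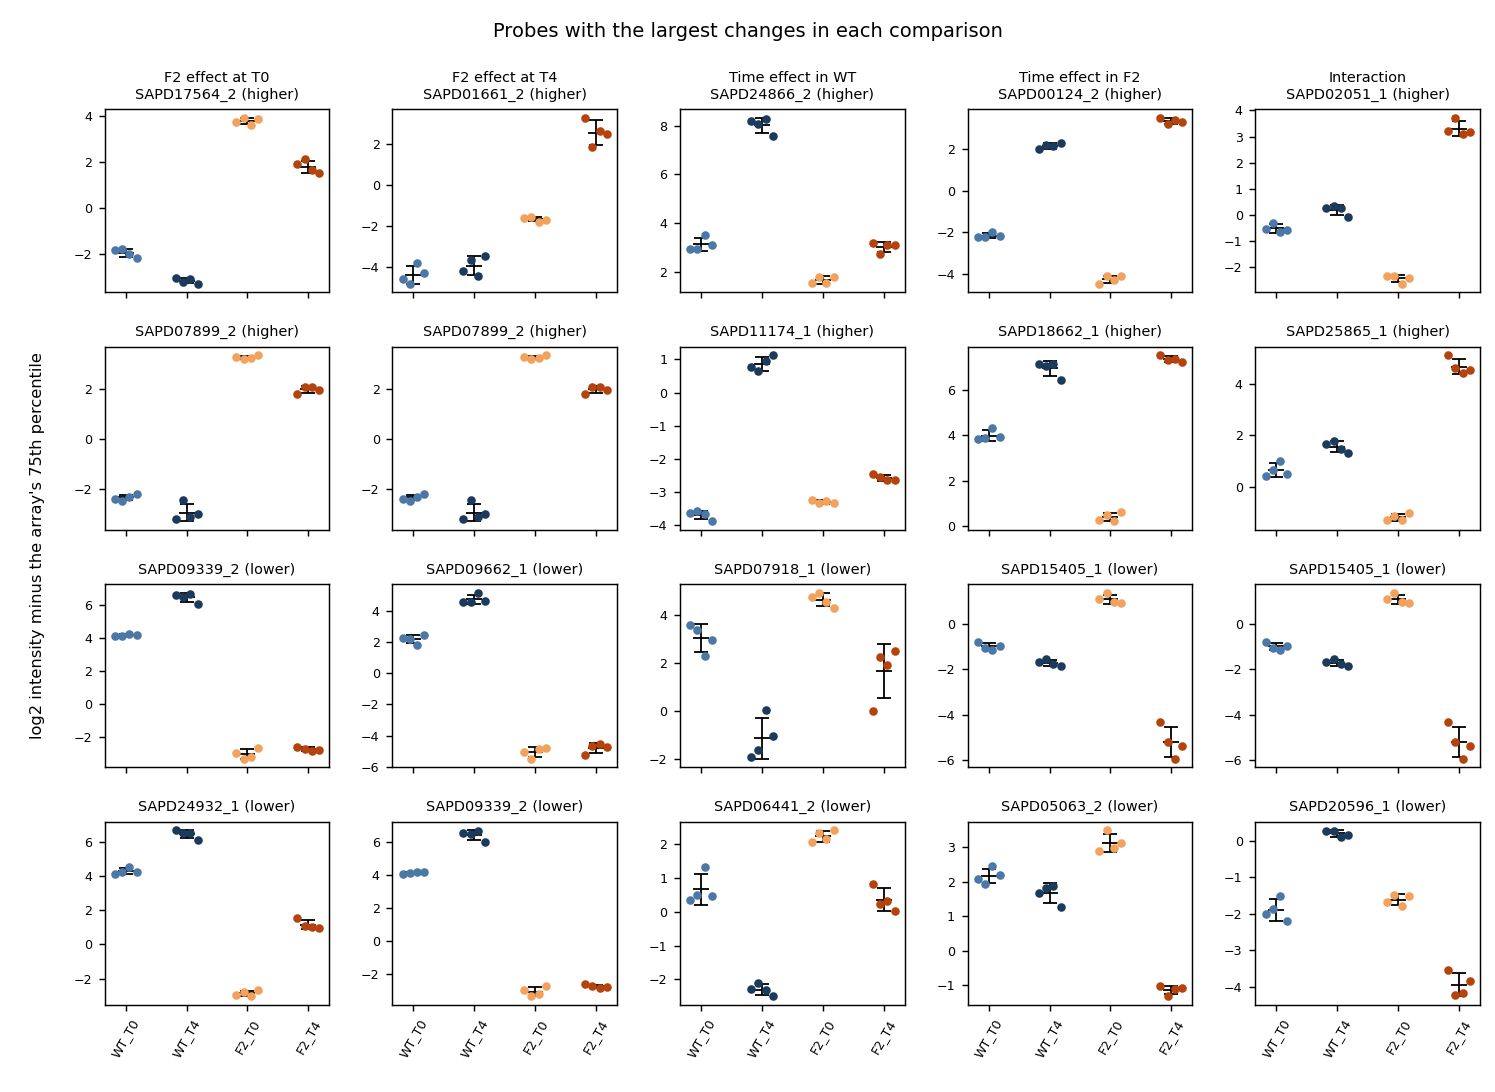
Log2 intensity minus the array's 75th percentile for the 2 rises and 2 falls named in each comparison (columns), by group. Points are the 4 arrays of a group, the horizontal mark is their mean and the bar 1 SD; SAPD15405_1, for example, stands at 1.104 in F2_T0 and at -5.22 in F2_T4.

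The last comparison tested whether the change over time differed between the lines, that is, whether the F2 difference itself changed from T0 to T4. Without a block such a change was called for 9643 probes, 4084 with a positive and 5559 with a negative interaction. This balance depended on the processing, with 3442 and 6003 after median scaling and 3763 and 3449 after normexp without dark spots. Among these, 2026 differed in the same direction at both times but by unequal amounts, 1086 differed in opposite directions, 3088 were called at T0 alone, 2693 at T4 alone and 750 at neither time. SAPD02051_1 (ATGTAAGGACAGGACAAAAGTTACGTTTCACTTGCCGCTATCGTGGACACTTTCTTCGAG) was lower in F2 at T0 by a log2 fold change of -1.90 and higher at T4 by 3.11, an interaction of 5.01 (SE 0.20, limma adjusted p = 1.72e-09). SAPD25865_1 (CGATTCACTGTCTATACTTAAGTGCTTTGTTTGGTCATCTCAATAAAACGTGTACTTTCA) went from -1.84 to 3.11, an interaction of 4.95 (SE 0.23, limma adjusted p = 5.42e-09). SAPD15405_1 went from 2.09 to -3.51, an interaction of -5.60 (SE 0.35, limma adjusted p = 7.26e-08). SAPD20596_1 (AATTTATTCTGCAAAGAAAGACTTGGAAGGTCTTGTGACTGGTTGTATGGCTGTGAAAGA) measured 0.28 at T0 (adjusted p = 0.176) and -4.13 at T4, an interaction of -4.41 (SE 0.23, limma adjusted p = 1.11e-08). In WT it rose by 2.09 over the 4 weeks, and in F2 it fell by 2.32.

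Scan day as a block removed a larger share of calls here than in any other comparison. The scan day 6 arrays all belonged to WT_T0 (3) and F2_T4 (2), which enter the interaction with the same sign. A difference of that day from the others would therefore add directly to the interaction without a block. With slide as a block 1274 calls were made. With scan day as a block the count fell to 3081, of which 1583 were positive and 1498 negative, and 1495 and 1406 of these were called in the same direction without the block. No slide or scan day held all 4 groups, so no value within one could be had.

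**Figure D4:**
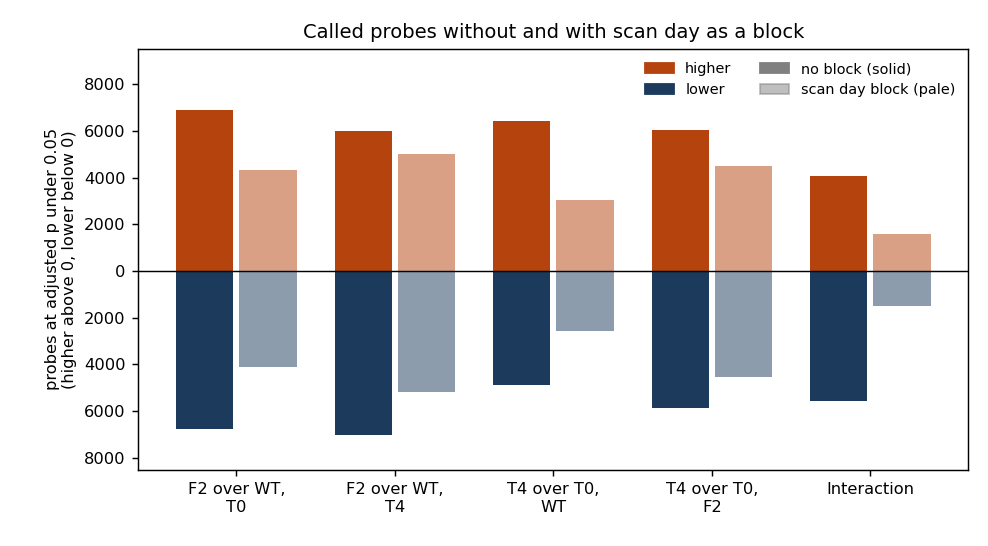
Number of probes at an adjusted p under 0.05 in each comparison, higher above 0 and lower below 0, without a block (solid) and with scan day as a block (pale). The interaction fell from 9643 to 3081 calls and the F2 difference at T4 from 12988 to 10193.

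Paired probes of one transcript gave a measure of probe error alone, since both are read on the same arrays and share any difference of slide, scan day or pool. For 13331 identifier stems both probes were tested, and their log2 fold changes correlated between r = 0.769 for the interaction and r = 0.910 for the time effect in F2. Randomly matched probes gave between -0.0077 and 0.0096. In the F2 difference at T0, both probes were called higher for 2706 stems and lower for 2624, and in opposite directions for 19. At T4 the numbers were 2217, 2493 and 30. For culture time they were 1919, 1562 and 38 in WT and 2385, 2342 and 15 in F2. For the interaction they were 1293, 1541 and 37. Many stems had only 1 of their 2 probes called: 2530 for the F2 difference at T0 and 2696 at T4. For culture time this held for 3305 stems in WT, against 3519 with both called, and for 2066 in F2. For the interaction it held for 3105 stems, against 2871 with both called.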

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

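The tests on scan day differences by scan day itself and by probe GC content, and the test of the background on WT_T4 replicate 2, were chosen after the result was seen; the others were set before. No regrouping of the arrays called as many probes as the real groups. A regrouping that mixes 2 groups moves their difference into the spread, which itself lowers its count. These regroupings also leave slide and scan day out, so they do not exclude a part due to either. For F2 over WT at T0, 1 of 35 splits of the 8 arrays, the real one, called as many as 13682 probes, and the highest other called 0. At T4 it was 1 of 35, with 12988 against 1602. For culture time it was 1 of 35 in WT, with 11271 against 3141, and 1 of 35 in F2, with 11915 against 1. The highest other split for WT set the 3 scan day 6 arrays of WT_T0 and WT_T4 replicate 3 against the rest, and the highest other at T4 joined F2_T4 replicate 1 with the WT_T4 arrays 1, 2 and 4; both follow scan day in part, and the blocked counts were 5586 and 10193.

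Without a block, the interaction test called 9643 probes as having an F2 difference that changed from T0 to T4. Of 100 orders of the residual profiles, the real one alone gave as many (1), and the highest other gave 3791; these orders ignore slide and scan day, and a fit with scan day as a block called 3081. The probes with the largest interactions were SAPD02051_1 (5.01), SAPD25865_1 (4.95), SAPD15405_1 (-5.60) and SAPD20596_1 (-4.41), on the log2 scale.

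Arrays of one group differed by scan day. Between scan days 6 and 4, 4359 probes (14.6%) differed over 2-fold within WT_T0, and 5064 within F2_T4, where each group had 1 array on day 4; 3236 did so in both groups in the same direction and 50 in opposite directions. The 2 sets of differences come from separate arrays and correlated at 0.817 across probes, which is consistent with a scan day batch. Probe GC content explained at most 0.50% of their variance, and after quantile normalization the correlation was still 0.794, which argues against GC content and array scaling. The day 4 arrays concerned are both on slide 4 and the day 6 arrays on slides 8 and 9, so day and slide cannot be told apart here. Whether the day stands for slide, scanning, labelling or the culture of the pools stays open, and no biological explanation was tested.

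With scan day as a block the interaction had 3081 calls, against 9643 without. Lost degrees of freedom and uneven days may account for the drop: 25 of 100 shuffles of the day labels over the arrays, the real one included, left as few calls, with a median of 4387 in the others. A part due to batch differences taken for interaction stays open, since the highest shuffle gave 12711.

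On the quality-control spots outside the main measurement, 24 of 40 were well above background on WT_T4 replicate 2 and 12 on WT_T4 replicate 4, against at most 3 on any other array. A raised background on replicate 2 is a candidate explanation: the 1st percentile of its probes' signal over local background was 44.1, against 3.80 to 12.6 on the others. Without that array, 8687 probes were called for culture time in WT. On WT_T4 replicate 4 the 1st percentile was 11.3, inside the range of the others, so it showed no raised background by this measure. What brought its 12 spots above background was not tested further.

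In 3 of 76 groups of 4 arrays tested, 1 array stood far from the others, where chance gives about 5%. SAPD09662_1 measured 5.185 on WT_T4 replicate 3 and 4.59 to 4.62 on the others. SAPD06441_2 measured 1.33 on WT_T0 replicate 3 and 0.35 to 0.50 on the others. SAPD18662_1 measured 6.42 on WT_T4 replicate 4 and 7.07 to 7.14 on the others.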

How the results depend on the processing

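The 20 log2 fold changes for which single probes were named kept their sign and their side of the threshold in all 654 values from other settings (6 combinations gave no value). Values of those probes in other comparisons were not rerun. These 20 were chosen as the largest changes past the threshold, so their stability of sign and call says little about the other called probes. The sizes of some of the 20 depended on the setting. SAPD09662_1 at T4 ran from -9.71 to -6.81, SAPD01661_2 at T4 from 4.09 to 6.76 and SAPD00124_2 over time in F2 from 5.87 to 7.75. SAPD18662_1 over time in F2 moved less, from 6.72 to 7.31. Counts are given below in the order F2 over WT at T0 and T4, culture time in WT and F2, and interaction, against 13682, 12988, 11271, 11915 and 9643. Normexp moved all 5, to 3701, 2251, 1809, 2992 and 875. On 4 arrays it set the 5th percentile of log2 signal at 8.65 to 10.5, against 3.11 to 4.91 on the others. Those 4 arrays held 3 to 12 spots far darker than their surroundings. F2_T0 replicate 4 also held 3 such spots, with a 5th percentile of 4.91. With such spots left out, chosen after seeing the data, the counts were 12402, 10695, 8201, 10041 and 7212. Those spots therefore accounted for most of the drop, though all 5 counts stayed below the main ones. For time in WT, 3755 were then higher and 4446 lower, against 6407 and 4864. Slide as a block gave 7295, 8352, 3625, 7511 and 1274, and correlations of 0.577 between the F2 differences at T0 and T4 and 0.413 between the time effects, against 0.387 and 0.201. Scan day as a block moved F2 over WT at T0 to 8458, time in WT to 5586 and the interaction to 3081. The cause of the changes under either block was tested only for the interaction with scan day. Averaging the probes of one stem gave 7309, 7138, 6172, 6366 and 5283, from fewer features tested. Array weights raised the interaction to 16761. The lowest weights went to F2_T4 replicate 1 (0.29) and WT_T0 replicate 3 (0.322), the scan day 4 arrays of their groups. Weighting thus came close to leaving those arrays out, though the cause of the rise was not tested. No other setting changed a number of called probes by a factor over 1.5. Without the scan day 4 arrays, also chosen afterwards, the interaction had 13207 calls, and the correlation between the time effects fell to 0.0256. That between the F2 differences fell to 0.252, as it did with array weights. Leaving these arrays out put WT_T0 on scan day 6 alone, which ties day more closely to group than in the main fit. With jackknife SDs of 0.203 and 0.175 neither correlation is well determined.

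Leaving out 1 array gave 12020 to 15122, 11107 to 15081, 7803 to 13886, 10509 to 12333 and 7243 to 12620 calls, and correlations of 0.288 to 0.442 and 0.0583 to 0.288. Quantile normalization moved the median of all probes at T4 by 0.12. Replicate numbers did not pair the arrays: deviations from the group mean correlated above 0.1 in 11 of 24 same-numbered pairs, and the best match in another group had the same number in 13 of 48 cases. With the replicate block the counts were 13207, 12286, 10158, 11520 and 8517. The probes detected in one line alone numbered 65, but 217 with 1 exception allowed per line and 149 without the scan day 4 arrays, both chosen after seeing the data. The planned gene list tests were not run, since no probe could be named. Signal over background limits the rest: 9567 probes were too dim to test.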

Other observations

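The tests below were set before their results were seen, except the comparison of the F2 difference at T4 with the change over time in WT, which was drawn on afterwards. Many probes that set F2 apart at T0 changed in the opposite direction over the next 4 weeks. Of the 2331 probes at least 2-fold higher in F2 at T0, 1169 then fell in F2, 226 rose further and 936 were not called for time. Of the 2882 at least 2-fold lower, 1628 rose, 141 fell further and 1113 were not called. In WT, 529 of the 2331 fell and 649 rose, and 936 of the 2882 rose and 530 fell. SAPD24932_1, for instance, rose by 4.02 on the log2 scale in F2. It also rose by 2.16 in WT, and its log2 fold change of F2 over WT was still -5.28 at T4. The F2_T0 arrays enter both the choice of the 2331 and 2882 probes and their later change in F2, which alone favours opposite directions. The WT_T0 arrays enter both that choice and the change in WT, which alone favours the same direction.

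A hypothesis is that the transfected line partly returned toward the control state. Both comparisons use the F2_T0 arrays, which alone ties them: the log2 fold changes had a covariance of -0.462, where unchanged groups that share arrays gave -0.3 to 0.0207 in 100 simulations. With the F2_T0 arrays divided between the comparisons, the covariance was at most -0.424 in 6 divisions, below every simulated value, and the correlation at most -0.464 (-0.528 undivided). The simulated correlations of unchanged groups that share arrays ran from -0.883 to 0.631, with a median of -0.51. Undivided correlations are therefore not evidence by themselves. Scan day was tested by taking the later change inside day 5 alone (1 F2_T4 and 2 F2_T0 arrays) and the T0 difference from the other 2 F2_T0 arrays, which gave -0.468. The covariance with divided arrays and the value from day 5 argue against shared arrays and scan day as the whole source. These 2 values do not single out a return of the transfected line, because a comparison without such a return gave much the same. The F2 difference at T4 and the change over time in WT, which share the WT_T4 arrays, correlated at -0.512, and at -0.501 to -0.351 with those arrays divided. Transcripts specific to one line at one time would give negative values in both cases. A partial return therefore stays open, as does any effect of the selection before T0.

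A second hypothesis was that F2 cells at T0 already resembled WT cells after 4 weeks. With the WT_T0 arrays divided, the correlation of F2_T0 over WT_T0 with WT_T4 over WT_T0 ran from -0.0247 to 0.137 in 6 divisions. It did not stay under the bound of 0.1 set beforehand in each division, nor reach 0.3 in any, so the data do not decide, though no strong resemblance was seen.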
